A study of Mus musculus with 48 samples.

How the data were processed

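The data were 48 RNA sequencing libraries from 16 populations of mouse hippocampal neurons, with 3 libraries per population that the series describes as biological replicates. Per the labels, fluorescent neurons were sorted by hand, ERCC spike-in RNA was added, and total RNA was amplified with Ovation RNA-seq v2 and sequenced on an Illumina HiSeq. The authors deposited a table of raw read counts per Ensembl gene, which was the measure for every test of genes, and a Cuffdiff table with 1 FPKM value per gene and library. FPKM values were scaled across libraries by the authors, since internal and external scaled fragments were equal in that table. The submitters' processing notes name TopHat2 2.0.6, Cuffdiff 2.1.1, HTSeq and DESeq2, and the builds NCBIM37 and mm9, but not the role of each. The strand used in counting was not given in the sources used here. Replicates are numbered as in the count table, 1 to 3, and each of the 48 count columns was most like the FPKM replicate numbered one less.

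The count table held 37620 genes, 92 ERCC sequences and 5 summary lines. ERCC and summary lines were kept out of library sizes and tests. Reads outside annotated genes made up 20.4% to 46.7% of uniquely mapped reads per library, ERCC sequences 0.0154% to 8.29% of reads in genes and ERCC together, and genes of the mitochondrial genome 8.3% to 24.5% of gene reads. Gene names came from a reference annotation of another build, joined by Ensembl identifier. It named 32897 identifiers, and the 4723 without a name held at most 0.81% of a library's reads. Gene coordinates were not used. The FPKM table held 37492 genes, of which 115 had values marked as failed (552 values), and these were left out. No 2 of the 48 columns were identical, and the lowest chi-square per degree of freedom between replicates was 13.0, far above the value of 1 that repeated counting of the same library would give. Library preparation dates, batches and the sex of the animals were not used.

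Each comparison was fitted with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests with robust dispersion, TMM scaling and the filterByExpr rule on the groups fitted. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Dorsal, intermediate and ventral CA1 shared 1 fit of 9 libraries. Amygdala-projecting, accumbens-projecting and ventral CA1 shared another. Proximal and distal CA1, superficial and deep CA1, postsubiculum-projecting and dorsal CA1, and PV and SST interneurons were fitted in pairs of 6 libraries. Dorsal and ventral CA1, CA3 and DG formed 1 fit of 18 libraries that gave the CA3 and DG long axes, the contrasts between regions, each averaged over dorsal and ventral cells, and the interactions of region and long axis. Where pairs of populations are set side by side, the counts of genes with at least a 3-fold difference came from fits of only the 2 groups compared. The biological coefficient of variation was 0.359 in the long-axis CA1 fit, 0.522 in proximal and distal, 0.488 in superficial and deep, 0.744 in the amygdala and accumbens fit, and 0.508 in the postsubiculum fit.

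CPM levels used the library sizes scaled by TMM over all 48 libraries. Where all libraries of the lower group had no read, the fold was set against a floor of 3 reads per library and is given as a lower bound. Where they had 1 to 3 reads together, the ratio was given with its 95% exact binomial interval. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Nothing in the labels says whether the 3 libraries of a population came from separate animals, so p-values measure only the spread between samples.

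Genes named in the report followed a rule. A gene had to be called, reach a mean of at least 10 CPM in the higher group, and have every library of one group above every library of the other, with all 6 against all 6 for contrasts between regions. Predicted genes, genes without a proper name, ribosomal protein genes, micro and small nucleolar RNA genes, mitochondrial genes and sex-linked genes were left out. The remainder was ranked by the size of the log2 fold change, and the first 10 per direction were taken for dorsal against ventral CA1, the first 8 for proximal against distal, superficial against deep and amygdala against accumbens, and the first 5 elsewhere. The list members with the smallest p and the label genes Pvalb, Sst, Prox1 and Calb1 were added. The rule, the comparisons and tests, the gene lists and most alternatives were set before the data were examined. Other genes named for marker levels were chosen after their values were seen.

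Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and beside it with an estimated correlation. A one-sided Fisher's exact test asked whether a list held more called genes than the other genes tested. Both were adjusted over the lists of a comparison, and lists needed at least 3 tested members. Lists of cell type markers covered CA1, CA2, CA3, DG granule and subiculum cells, GABAergic, PV and SST interneurons, astrocytes, oligodendrocytes, microglia, endothelium and choroid plexus. Functional lists covered long-axis dorsal and long-axis ventral genes, potassium channels, sodium and calcium channels, glutamate receptors, GABA receptors, monoamine and acetylcholine receptors, neuropeptides, neuropeptide receptors, cell adhesion, axon guidance, extracellular matrix, immediate-early genes, oxidative phosphorylation and sex-linked genes. Of 352 tests of a list in a comparison 98 passed by camera, 29 of them also with an estimated correlation, and 147 passed by Fisher's test. The calls that held with both correlations were as follows. Along the CA1 long axis they were long-axis dorsal genes and SST markers between the poles, GABAergic markers, SST markers and neuropeptides in the first step, and CA1 markers, long-axis dorsal genes, sodium and calcium channels and neuropeptides in the second. In CA3 they were CA1 markers, CA3 markers and both long-axis lists, and in DG long-axis ventral genes and oxidative phosphorylation. Between regions they were the markers of the regions compared, long-axis dorsal genes between CA1 and CA3, and GABAergic markers between CA3 and DG. PV and SST markers held in their own contrast, CA1 markers and long-axis dorsal genes in the interaction with CA3, and GABAergic markers and oxidative phosphorylation in the interaction with DG.

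Further measures described the axes. The position of intermediate CA1 was its distance from ventral as a share of the distance from ventral to dorsal on mean log2 CPM, over the genes called between the poles. Genes highest or lowest in intermediate CA1 were called in both steps with opposite signs, and the number expected took the called genes of the 2 steps as independent. In 20 simulations with no changed gene the count was taken in the same way. Overlap between axes was tested by the hypergeometric distribution. The long-axis score was the mean log2 CPM of the 100 genes with the smallest p higher in dorsal CA1 minus that of the 100 higher in ventral CA1.

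The procedure was tested on simulated data. Negative binomial counts were drawn with the means, library sizes and dispersions of the real libraries, 100 genes were changed 2-fold and 100 were changed 4-fold. Of these the procedure recovered 42 and 77 between dorsal and ventral CA1, where 6.3% of 127 calls were false. It recovered 34 and 72 between dorsal and intermediate CA1, 40 and 78 between intermediate and ventral CA1, 29 and 61 between proximal and distal cells, 22 and 53 between superficial and deep cells, and 7 and 39 between amygdala-projecting and accumbens-projecting cells. For postsubiculum-projecting cells it recovered 33 and 56, for the CA3 long axis 17 and 54, for the DG long axis 11 and 56, and for PV against SST cells 4 and 40. Contrasts between regions recovered 43 and 74 for CA1 against CA3, 28 and 67 for CA1 against DG, and 36 and 72 for CA3 against DG. Interactions recovered 4 and 23 with CA3 and 3 and 36 with DG. The false share was 0.9% to 10% over these comparisons. All groups of a fit were simulated with the same dispersion per gene, while the real groups differed in spread. Replicates correlated at 0.844 to 0.852 in dorsal DG and at 0.974 to 0.979 in dorsal CA3. The simulated shares therefore do not cover the effect of unequal spread within a fit. On the simulated counts of dorsal and ventral CA1, DESeq2 recovered 50 and 84 with 14.1% false calls, voom 40 and 72 with 6.7%, and the FPKM route 31 and 70 with 2.9%.

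Most alternatives changed 1 choice at a time. The DESeq2 test also brought its own filter, the FPKM route its own measure, test and filter, and the fit to all 48 libraries its own set of tested genes. Those planned were DESeq2's size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter beyond 1 read, all 48 libraries in 1 fit, limma voom with quality weights, limma on log2(FPKM + 1) for genes of mean FPKM at least 1, the replicate number as a block, and leaving out each library in turn. For the other measures they were other fold thresholds, numbers of genes and offsets, and the estimated correlation. Thinning of every library of a fit to the reads of the shallowest, removal of each library's trend of log count on exon length, and leaving out libraries for the position of intermediate cells and for the genes peaking there were added after seeing the data. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.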

Results

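The series sequenced 16 populations of hand-sorted mouse hippocampal neurons, with 3 libraries each. Of the 16 populations, 10 were CA1 pyramidal cells: dorsal, intermediate and ventral cells along the long axis, proximal and distal cells along the transverse axis, superficial and deep cells across the cell layer, and cells defined by a projection to the postsubiculum, the amygdala or the nucleus accumbens. The others were dorsal and ventral CA3 pyramidal cells, dorsal and ventral granule cells of the dentate gyrus (DG), and interneurons that express parvalbumin (PV) or somatostatin (SST). Reads counted in genes ranged from 5.12 to 31.98 M per library. The mean was 25.9 ± 3.99 M in dorsal CA1, 8.58 ± 1.85 M in intermediate CA1 and 7.01 ± 1.68 M in ventral CA1. Levels below are CPM, read counts scaled to a common library size, as mean ± SD over 3 libraries unless another number is given, and adjusted p-values come from edgeR. Each gene chosen by rank for a comparison of 2 groups separated every library of one group from every library of the other, which chance gives for 10% of genes with 3 libraries against 3.

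Marker genes mostly followed the names of the populations. Fibcd1 marked CA1, Mpped1 parted CA1 from CA3 and DG but was also read in SST and PV cells at 80.3 ± 13.4 and 51.7 ± 21.4 CPM, Iyd marked dorsal CA3, and Prox1, Dsp and Glis3 marked the granule cells, as the plot of marker genes across populations shows. Gad1, the main GABA-synthesising enzyme, reached 1130 CPM in PV cells and 595 CPM in SST cells but was also read in some pyramidal groups. It stood at 67.4 ± 47.1 CPM in deep CA1, where Gad2 stood at 353 ± 228 CPM, at 15.3 ± 26 CPM in proximal CA1 and at 14.5 ± 21.1 CPM in superficial CA1. Pvalb stood at 27.2 ± 46.9 CPM in proximal CA1, and Sst at 39.5 ± 67.4 CPM in deep CA1 and 174 ± 296 CPM in accumbens-projecting CA1. Single libraries carried most of these means, but not those of Gad1 and Gad2 in deep CA1. Proximal replicate 1 held 81.3 CPM of Pvalb and 45.3 CPM of Gad1, deep replicate 1 held 117 CPM of Sst, superficial replicate 3 held 38.9 CPM of Gad1 and accumbens-projecting replicate 3 held 516 CPM of Sst. The other libraries of those groups held at most 0.18, 0.36, 0.815, 2.49 and 5.75 CPM of the same genes. PV cells held 652 ± 362 CPM of Sst. Gad1 was also read in dorsal and ventral DG, at 72.5 and 50.7 CPM. Endothelial and choroid plexus markers had too few measured members for a test in any comparison, and Cldn5 and Ttr stayed under 1 CPM in the mean of every population. Another endothelial gene, Kdr, stood at 65.1 ± 32.5 CPM in amygdala-projecting and 35.9 ± 22.3 CPM in accumbens-projecting cells, against 1.12 ± 1.93 CPM in ventral CA1, and Pecam1 reached 3.65 ± 3.57 CPM in amygdala-projecting cells.

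**Figure D1:**
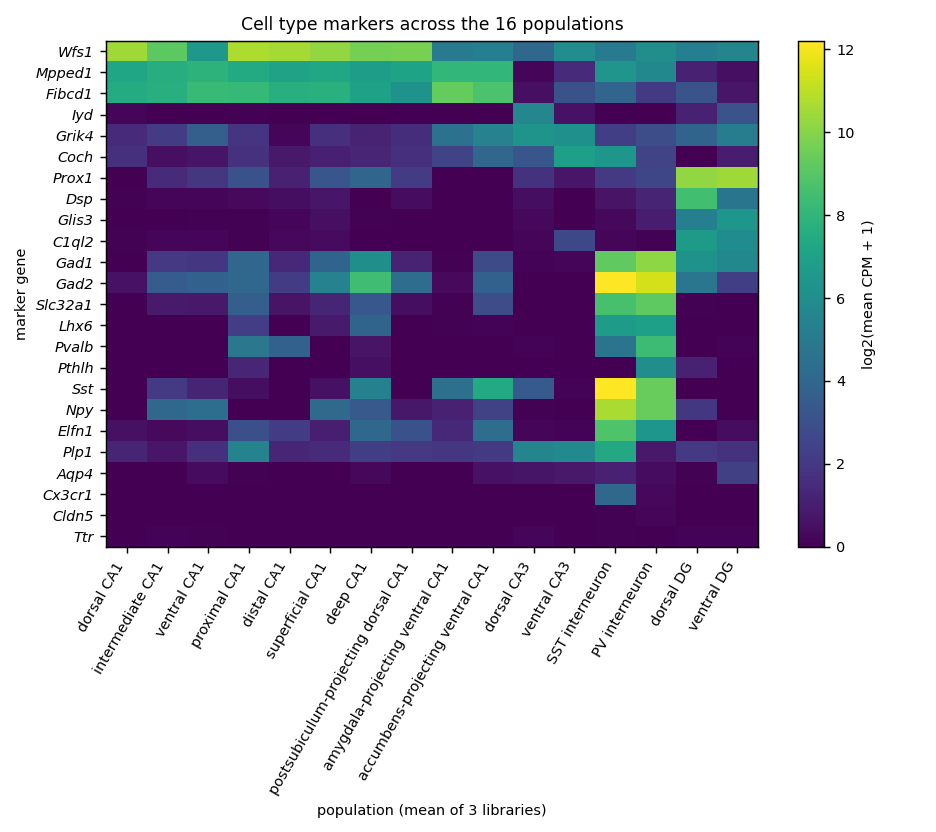
Mean level of 24 marker genes (vertical axis) in the 16 populations (horizontal axis), as colour on a log2 scale of mean CPM plus 1, over 3 libraries each. Interneuron genes such as Gad1 and Gad2 stand highest in PV and SST cells and are also visible in deep CA1.

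The first comparison was between the dorsal and ventral poles of CA1. Dorsal cells held 48.3 ± 4.28 CPM of Scn4b (ENSMUSG00000046480), a sodium channel beta subunit, and no ventral library had a read of it, which made it at least 114-fold higher (adjusted p = 0.00224). Lct (ENSMUSG00000026354), the lactase gene, stood at 124 ± 4.26 CPM in dorsal and 0.254 ± 0.295 CPM in ventral cells, 430-fold apart (adjusted p = 0.000232). In the other direction Npy (ENSMUSG00000029819), which encodes neuropeptide Y, had no read in dorsal libraries and 20.1 ± 0.219 CPM in ventral ones, at least 169-fold higher (adjusted p = 8.32e-09). Proximal, distal and postsubiculum-projecting CA1 went with dorsal CA1, at 0, 0.0156 and 0.704 CPM of Npy. Superficial, deep and amygdala-projecting cells, at 17.8 ± 1.73, 9.55 ± 2.21 and 1.17 ± 2.03 CPM, did not follow the long axis. Ndrg1 (ENSMUSG00000005125) rose from 0.106 to 84.7 ± 21.6 CPM, a 772-fold difference (adjusted p = 0.000468). Dcn, which encodes the matrix proteoglycan decorin, rose from 1.12 ± 1.78 to 350 ± 85.9 CPM, a 347-fold difference (adjusted p = 0.0203). It lost its call without dorsal replicate 1 or 2 or ventral replicate 3.

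Other genes ranked highest in dorsal CA1 were the axon guidance receptor Robo3 at 19.4 ± 5 CPM, the matrix proteoglycan Bcan at 25 ± 3.85 CPM, the integrin subunit Itga7 at 13.3 ± 5.11 CPM, and Olfm3, Plekhg1, Dnah6, Egfl6 and the serotonin receptor Htr1f at 54.5, 148, 20.3, 23.2 and 13.6 CPM. Plekhg1 was 40.6-fold higher than in ventral cells and Olfm3 55.7-fold. Those ranked highest in ventral CA1 were the insulin receptor substrate Irs4 at 14 ± 1.68 CPM, Igfbp5 at 32.8 ± 2.75 CPM, the deiodinase Dio3 at 17.6 ± 9.89 CPM, the growth factor Kitl at 12 ± 9.63 CPM, Kctd12b at 11.4 ± 3.64 CPM, Lgals3bp at 11.2 ± 7.88 CPM and the collagen gene Col6a1 at 20 ± 15.9 CPM. No dorsal library had a read of Irs4, at least 118-fold under the ventral level, but neither had any amygdala-projecting or accumbens-projecting library, and superficial cells held 13.2 ± 2.8 CPM. Igfbp5 had so few dorsal reads that counting error placed its ratio between 348 and 10400. In all, 1837 of 12149 genes were called, 871 higher in dorsal and 966 higher in ventral cells, and 685 of them differed at least 3-fold. Calb1, the calbindin gene, was higher in ventral than in dorsal cells (69.8 ± 18.2 against 173 ± 25.7 CPM, adjusted p = 0.018), a call lost without dorsal replicate 1 or 2 or ventral replicate 1 or 3.

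**Figure D2:**
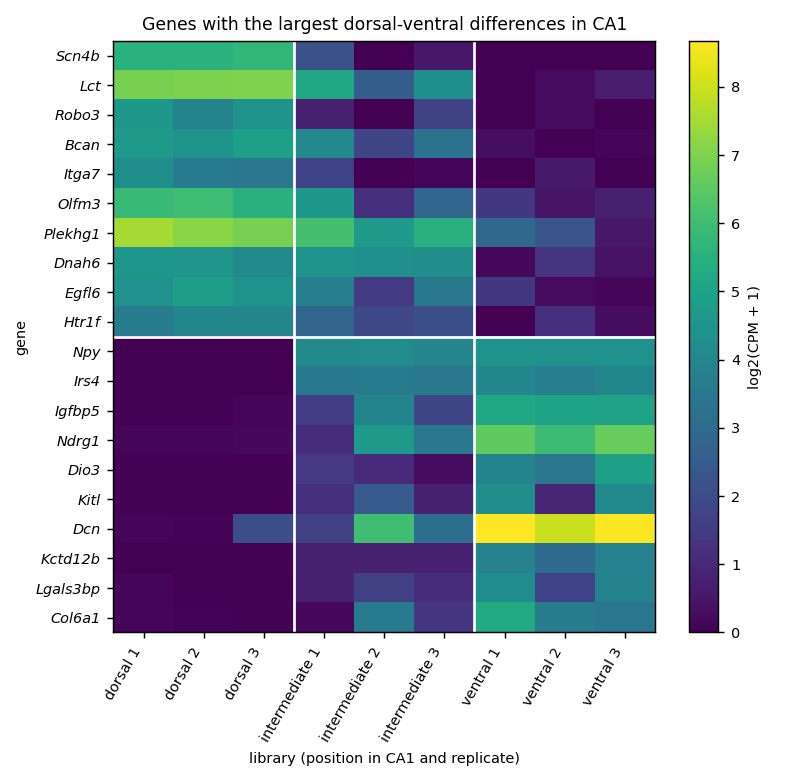
Levels of the 20 genes with the largest called differences between dorsal and ventral CA1 (vertical axis) in the 9 long-axis CA1 libraries (horizontal axis), as colour on a log2 scale of CPM plus 1. The upper 10 genes were higher in dorsal and the lower 10 in ventral cells, and intermediate libraries mostly stand between them.

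Ion channel genes differed along this axis in both directions. Of 59 potassium channel genes 18 were higher in dorsal and 16 in ventral CA1, and 38 were called when adjusted over the list alone. Kcnd2, which carries A-type current, stood at 468 ± 5.84 CPM in dorsal and 176 ± 21.2 CPM in ventral cells (adjusted p = 9.15e-08), while Kcnc4 rose from 0.174 to 43.6 ± 10 CPM in ventral cells (adjusted p = 1.82e-08). That share of called genes exceeded the background (Fisher adjusted p = 6.32e-13), while camera, which tests for a common direction, gave adjusted p = 0.955. Among 29 sodium and calcium channel genes 10 were higher in dorsal and 6 in ventral cells, 19 adjusted over the list alone, led by Scn3b at 1170 ± 31.8 against 286 ± 35.7 CPM (adjusted p = 1.22e-09). Camera placed that list toward dorsal (adjusted p = 0.0233; adjusted p = 0.0938 with an estimated correlation).

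Receptor genes split by subunit. Of 22 glutamate receptor genes 4 were higher in dorsal and 7 in ventral CA1, 12 adjusted over the list alone (camera adjusted p = 0.00482 toward ventral; adjusted p = 0.156 with an estimated correlation). The NMDA receptor subunit Grin2a stood at 1160 ± 22.4 CPM in dorsal and 570 ± 85.8 CPM in ventral cells, and Grin3a at 21.6 ± 6.39 and 233 ± 9.6 CPM. Of 16 GABA receptor genes 8 were higher in dorsal and 5 in ventral cells, 14 adjusted over the list alone (Fisher adjusted p = 3.9e-08), with Gabra3 at 32.7 ± 1.74 against 128 ± 28.4 CPM. Of 24 monoamine and acetylcholine receptor genes 7 were higher in dorsal and 4 in ventral cells, 12 adjusted over the list alone (camera adjusted p = 0.87), among them Chrna5 at 21.6 ± 3.84 against 2.64 ± 0.565 CPM and Htr5a at 19.9 ± 2.87 against 52.2 ± 18.3 CPM. Of 20 neuropeptide receptor genes 8 were higher in ventral and 1 in dorsal cells, 10 adjusted over the list alone (camera adjusted p = 0.00482; adjusted p = 0.0938 with an estimated correlation). The oxytocin receptor Oxtr rose from 0.381 ± 0.27 to 22.6 ± 11.3 CPM there (adjusted p = 1.26e-05). Of 11 neuropeptide genes 5 were higher in dorsal and 4 in ventral cells, 11 adjusted over the list alone (camera adjusted p = 0.976), with Bdnf, the neurotrophin, at 104 ± 10.3 against 40.4 ± 16.1 CPM.

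Genes for cell contacts and matrix were called often. Of 63 cell adhesion genes 14 were higher in dorsal and 25 in ventral CA1, 42 adjusted over the list alone (Fisher adjusted p = 5.51e-16, camera adjusted p = 0.0597). Nrxn3 stood at 521 ± 51 against 104 ± 5.97 CPM and Kirrel3 at 1.4 ± 0.586 against 78.1 ± 4.34 CPM. Axon guidance genes split 12 to 17 of 59, 36 adjusted over the list alone (Fisher adjusted p = 5.22e-09, camera adjusted p = 0.473), with Epha5 at 317 ± 19.4 against 122 ± 18.6 CPM and Slit2 at 14.3 ± 4.22 against 170 ± 30.6 CPM. Of 36 extracellular matrix genes 15 were higher in ventral and 3 in dorsal cells, 21 adjusted over the list alone (camera adjusted p = 0.00025; adjusted p = 0.156 with an estimated correlation), with Spock1 at 6.02 ± 0.306 against 115 ± 52.2 CPM. Of 18 immediate-early genes 3 were higher in dorsal and 3 in ventral cells, 7 adjusted over the list alone (camera adjusted p = 0.442), with Egr1 at 506 ± 190 against 126 ± 20.9 CPM and Fosl2 at 14.2 ± 6.87 against 134 ± 43.1 CPM. By edgeR none of the 79 oxidative phosphorylation genes and none of the 5 sex-linked genes was called, 0 adjusted over either list alone (camera adjusted p = 0.921 for both).

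Lists named for the long axis were partly chosen from this study and are not independent evidence of direction. Of the 6 dorsal genes 5 were higher in dorsal CA1 and 1, Ccn3, a matricellular protein gene, was higher in ventral CA1 (103 ± 6.29 against 417 ± 35 CPM). All 6 were called when adjusted over the list alone (camera adjusted p = 0.000128; adjusted p = 0.0438 with an estimated correlation). Wfs1 stood at 1430 ± 70.5 against 89.7 ± 21.6 CPM. Of 6 measured ventral genes 3 were higher in ventral cells and 4 adjusted over the list alone (camera adjusted p = 0.00162; adjusted p = 0.143 with an estimated correlation), with Etv1 at 241 ± 9.82 against 672 ± 124 CPM. CA1 markers were not evenly spread along the axis either, with 3 of 7 higher in dorsal, 2 higher in ventral and 5 called adjusted over the list alone (camera adjusted p = 0.0119; adjusted p = 0.0938 with an estimated correlation). Interneuron genes were read at low levels in ventral but hardly in dorsal CA1. All 3 measured GABAergic markers were higher in ventral cells, 3 adjusted over the list alone (camera adjusted p = 0.00223; adjusted p = 0.0938 with an estimated correlation), as were 3 of 5 SST interneuron markers, 3 adjusted over the list alone (camera adjusted p = 6.4e-05; adjusted p = 0.0438 with an estimated correlation). Gad2 stood at 0.492 ± 0.795 against 12.9 ± 1.54 CPM and Reln at 0.184 against 5.51 ± 0.501 CPM.

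Intermediate cells were compared with both poles. Npy and Irs4, absent from dorsal reads, were already at 16.1 ± 1.35 and 10.3 ± 0.219 CPM in intermediate cells, at least 135-fold and 86.9-fold higher than in dorsal ones. Enpp2, which makes the signalling lipid lysophosphatidic acid, fell from 88.9 ± 14.9 CPM in dorsal to 7.44 ± 1.22 CPM in intermediate cells, and Robo3 from 19.4 ± 5 to 1.01 ± 1.18 CPM. Between intermediate and ventral cells Dnah6 fell from 19.5 ± 0.881 to 0.646 CPM and Stac from 11.6 ± 2.31 to 0.731 ± 0.33 CPM, while the cadherin Cdh20 rose from 1.01 to 27.8 ± 5.3 CPM and Mctp1 from 3.01 ± 2.19 to 63.6 ± 18.4 CPM. In the first step 599 of 12149 genes were called, 205 higher in dorsal and 394 higher in intermediate cells, and in the second 611, of which 379 were higher in intermediate and 232 in ventral cells. Without dorsal replicate 1, dorsal replicate 3 or intermediate replicate 2 the first step called 321, 350 and 315 genes, and without intermediate replicate 1 the second called 399. Of the genes ranked for the first step, Scn4b, Itga7, Chd7, Ndrg1 and Adra1a lost their call in at least 1 omission of a library, as did Lct and Col23a1 for the second. In the fit to all 48 libraries 7 of the 10 genes ranked for the second step were not called, Dnah6, Stac and Cdh20 among them.

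Gene lists moved in both steps. In the first, 3 of 63 cell adhesion genes were higher in dorsal and 11 in intermediate cells, 23 adjusted over the list alone (camera adjusted p = 0.00413; adjusted p = 0.236 with an estimated correlation), and 1 of 36 extracellular matrix genes was higher in dorsal and 7 in intermediate cells, 12 adjusted over the list alone (camera adjusted p = 0.000224; adjusted p = 0.236 with an estimated correlation). Kirrel3 rose from 1.4 ± 0.586 to 32.8 ± 14.5 CPM and Sparcl1 from 73.8 ± 16 to 382 ± 49.9 CPM. Of 11 neuropeptide genes 4 were higher in intermediate cells and 1 in dorsal, 7 adjusted over the list alone (camera adjusted p = 0.000326; adjusted p = 0.0466 with an estimated correlation). Interneuron markers moved with that list. Of 3 GABAergic markers 2 were higher in intermediate cells, 2 adjusted over the list alone (camera adjusted p = 0.000224; adjusted p = 0.0466 with an estimated correlation), as were 3 of 5 SST interneuron markers, with 3 against 1 adjusted over the list alone (camera adjusted p = 3.9e-07; adjusted p = 0.0255 with an estimated correlation). Gad2 rose from 0.492 to 10.7 CPM, Reln from 0.184 to 5.43 CPM and Sst, which like Npy is also a neuropeptide gene, from no read to 3.18 CPM. In the second step 4 neuropeptide genes were higher in intermediate than in ventral cells and none the other way, 5 adjusted over the list alone (camera adjusted p = 0.000499; adjusted p = 0.0402 with an estimated correlation), among them Chgb at 824 ± 77.1 against 390 ± 57.8 CPM. Of 29 sodium and calcium channel genes 5 fell and 1 rose from intermediate to ventral, 9 adjusted over the list alone (camera adjusted p = 0.00212; adjusted p = 0.0402 with an estimated correlation), with Scn3b at 765 ± 132 against 286 ± 35.7 CPM. Cell adhesion genes split 11 to 9 of 63, 27 adjusted over the list alone (Fisher adjusted p = 2.92e-10).

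Most genes called between the poles were graded. Of the 1837 genes, 1606, or 87.4%, had an intermediate mean between the dorsal and ventral means. With 0 as the ventral and 1 as the dorsal level, the median position of intermediate cells was 0.509 (quartiles 0.313 and 0.712), with an SD over the 3 intermediate libraries of 0.104. As a reference, for 81 of the 135 genes called between proximal and distal cells, or 60%, the intermediate mean lay between those groups. Both steps called 157 of the same genes, 132 of them in the same direction. Genes higher in dorsal cells had a median of 0.61 and those higher in ventral cells 0.424. The single intermediate libraries gave 0.614, 0.407 and 0.527. Some genes peaked between the poles: 16 were higher in intermediate cells than at both poles and 9 were lower. Vipr2, a receptor for vasoactive intestinal peptide, stood at 0.572 ± 0.268, 16.8 ± 3.13 and 0.678 ± 0.5 CPM from dorsal to ventral. The adhesion gene Cntnap5b stood at 25.4 ± 6.15, 77.6 ± 24.9 and 31.3 ± 4.26 CPM, and Trps1 was lowest in the middle at 26.8 ± 8.42, 7.76 ± 2.17 and 25 ± 8.49 CPM. Of the 16 highest, Eno1b, Gm4735 and Gm11223 are uncertain because near-identical gene copies may share their reads, which was not tested. If the called genes of the 2 steps were independent, 12.3 higher and 3.9 lower genes would be expected. Both steps share the intermediate libraries, which favours such genes, though 20 simulations without any changed gene gave at most 1. Those simulations hold no gene that differs in 1 step, so neither number is a full reference. The 25 genes of both kinds fell to 12 and 15 without dorsal replicates 1 and 2, to 8 without intermediate replicate 2 and to 16 without ventral replicate 2. In the fit to all 48 libraries together the count was 2.

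The transverse axis was tested by comparing proximal cells, near CA3, with distal cells, near the subiculum. Car8, a carbonic anhydrase-related protein gene, was the clearest distal gene, at 40.5 ± 4.39 CPM against 0.228 ± 0.345 CPM in proximal cells, 176-fold apart (adjusted p = 0.00261). Ndst4, a heparan sulfate enzyme, stood at 204 ± 57.8 CPM in distal and 53.7 ± 7.47 CPM in proximal cells (adjusted p = 0.00219), and Nr4a2, an activity-regulated nuclear receptor, at 186 ± 52.4 and 58.9 ± 14.9 CPM (adjusted p = 0.00924). Both lost their call in the fit to all 48 libraries, as did 4 of the other 14 ranked genes, and on FPKM 8 of 16 lost theirs. Hapln4, a link protein of the neuronal matrix, was higher in proximal cells at 99.7 ± 4.5 against 21.5 ± 4.78 CPM (adjusted p = 0.00191), as was the netrin receptor Unc5a at 171 ± 10.1 against 63.1 ± 14.4 CPM (adjusted p = 0.00602). The largest proximal ratios, those of Atp6v0c-ps2 and Tuba1c at 184-fold and 79.9-fold, are uncertain because near-identical copies may share their reads, which was not tested. In all, 135 of 12710 genes were called, 104 higher in proximal and 31 higher in distal cells, and 34 differed at least 3-fold. The X-linked gene Xist stood at 643 and 769 CPM in proximal replicates 1 and 2 and at 6.24 CPM in replicate 3. Every distal library held more of the Y-linked gene Ddx3y than of Xist, which reached at most 4.22 CPM there. Sex-linked expression thus ran partly with this axis, and the part of sex was not tested.

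Of 18 immediate-early genes 2 were higher in proximal and 1, Nr4a2, in distal cells, with 12 called adjusted over the list alone (camera adjusted p = 5.21e-07 toward proximal; adjusted p = 0.276 with an estimated correlation). Of 32 sodium and calcium channel genes 2 were higher in proximal cells, 4 adjusted over the list alone (camera adjusted p = 3.95e-07; adjusted p = 0.2 with an estimated correlation). Of 18 neuropeptide receptor genes 1, the opioid receptor Oprd1, was called, 3 adjusted over the list alone (camera adjusted p = 0.000133; adjusted p = 0.256 with an estimated correlation). None of 81 oxidative phosphorylation genes was called by edgeR over all genes or adjusted over the list alone, though camera placed the list toward distal (adjusted p = 3.68e-07; adjusted p = 0.256 with an estimated correlation). Axon guidance genes had 1 of 55 higher in each direction, 13 adjusted over the list alone (camera adjusted p = 0.0172; adjusted p = 0.256 with an estimated correlation), and extracellular matrix genes 2 of 31 each way, 5 adjusted over the list alone (Fisher adjusted p = 0.00705). PV interneuron markers had 0 of 4 called, 3 adjusted over the list alone (camera adjusted p = 0.0765), with Pvalb at 27.2 ± 46.9 against 12.8 ± 2.27 CPM. The direction of Pvalb rested on proximal replicate 1, without which its log2 difference turned from 1.13 to -6.42. The other ranked genes (Oprd1, Rbms3, Eno1b, Kit, Cfap54, Decr1, Spock3, Sema3a, Col11a1, Osbpl3 and Slc38a2) each lost their call when at least 1 library was left out, as did Nr4a2 without distal replicate 1. The count fell to 68, 38 and 81 without proximal replicates 1, 2 and 3, to 29 and 16 without distal replicates 1 and 2, and to 94 without distal replicate 3.

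The radial axis was tested by comparing superficial with deep cells of the CA1 layer. Deep cells held St18, a zinc finger transcription factor gene, at 83.2 ± 10.9 CPM against 1.44 ± 1.09 CPM in superficial cells, 58.5-fold apart (adjusted p = 0.00011). Stoml3 and the growth factor Igf1 had no read in superficial libraries and stood at 15.9 ± 4.53 and 11 ± 3.58 CPM in deep ones, at least 121-fold and 83.2-fold higher. Superficial cells held more Anln, 105 ± 15.6 against 11.2 ± 5.37 CPM (adjusted p = 0.000885), more of the receptor phosphatase Ptprk, 50.2 ± 23.2 against 3.62 ± 1.03 CPM (adjusted p = 0.00101), and more Calb1, 92.7 ± 5.02 against 15.5 ± 8.26 CPM (adjusted p = 0.00385). Dgkk and Irs4 stood at 12.4 ± 1.3 and 13.2 ± 2.8 CPM in superficial cells, 112-fold and 86-fold above deep ones. In the fit to all 48 libraries 9 of the 16 ranked genes lost their call, Stoml3, Dgkk and Irs4 among them, and on FPKM 7 of 14, Igf1 and Irs4 among them. In all, 311 of 12533 genes were called, 111 higher in superficial and 200 in deep cells, and 146 differed at least 3-fold. None of the 3 deep libraries was most like its own group by correlation (0 of 3), against 2 of 3 superficial ones.

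Receptors for transmitters again went both ways. The serotonin receptor Htr1a stood at 213 ± 39 CPM in superficial and 41.4 ± 9.99 CPM in deep cells (adjusted p = 0.000226) and Htr2c at 2.56 ± 1.01 and 34.4 ± 18.5 CPM (adjusted p = 0.00273), among 28 monoamine and acetylcholine receptor genes with 1 higher in superficial and 3 in deep cells, 8 adjusted over the list alone (camera adjusted p = 0.215). Of 18 neuropeptide receptor genes 2 were higher in superficial cells, 4 adjusted over the list alone (camera adjusted p = 5.95e-05; adjusted p = 0.102 with an estimated correlation), including Npy2r at 94.1 ± 17.9 against 22.1 ± 2.15 CPM. Of 23 glutamate receptor genes 3 were higher in deep cells, 7 adjusted over the list alone (camera adjusted p = 0.0175; adjusted p = 0.14 with an estimated correlation), led by Grik3 at 0.504 against 33.2 ± 28.3 CPM. Of 35 extracellular matrix genes 6 were higher in deep cells and 0 the other way, 10 adjusted over the list alone (camera adjusted p = 1.11e-05; adjusted p = 0.0993 with an estimated correlation), with Spock3 at 2.62 ± 1.21 against 29.6 ± 7.17 CPM. Cell adhesion genes split 3 to 8 of 65, 20 adjusted over the list alone (Fisher adjusted p = 1.15e-05), with Pcdh17 at 60.6 ± 10.4 against 197 ± 30.8 CPM. None of 6 GABAergic markers was called by edgeR, 3 adjusted over the list alone and all 3 higher in deep cells (camera adjusted p = 1.29e-05; adjusted p = 0.209 with an estimated correlation), and Gad1 was read at 67.4 ± 47.1 CPM in those cells. Astrocyte markers had 0 of 3 called, 0 adjusted over the list alone (camera adjusted p = 0.801). Without superficial replicates 1, 2 and 3 the count was 105, 85 and 145, and Reln, Ddit4l, Eya1, Prrx1, Efcab6, Cyp26b1 and Met lost their call in at least 1 omission of a library.

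The axes of CA1 were then set against each other, using fits that share no library. Of the genes called on both axes 28 were higher in both ventral and proximal cells where 6.7 were expected (hypergeometric adjusted p = 1.28e-10), and 12 genes were higher in both dorsal and distal cells where 2.2 were expected (adjusted p = 9e-07). A further 16 were higher in both dorsal and proximal cells where 7.2 were expected (adjusted p = 0.00275). In the fit to all 48 libraries this last overlap fell to 4 genes where 1.7 were expected (adjusted p = 0.11), while ventral and distal cells shared 6 where 0.3 were expected (adjusted p = 2.7e-07), against 4 where 2.1 were expected before. Across 11713 genes the log2 differences of the long and the transverse axis correlated at -0.15. Unc5a was higher in ventral and in proximal cells, while Ndst4 was higher in dorsal, in distal and in deep cells, the last at a log2 difference of -3.63 from superficial to deep. Genes called on both the long and the radial axis numbered 57 for ventral and deep, 42 for dorsal and superficial, 34 for dorsal and deep and 29 for ventral and superficial cells, where 8.1 to 13 were expected, and the correlation was 0.10. In the fit to all 48 libraries these counts were 20, 5, 0 and 5, so no shared gene was left for dorsal and deep cells. Proximal and superficial cells shared 12 genes where 0.8 were expected (adjusted p = 1.28e-10), and distal and deep cells shared 7 where 0.4 were expected (adjusted p = 3.62e-07). Their correlation was 0.10, and -0.01 in the fit to all 48 libraries. These p-values treat genes as independent, which genes expressed together are not.

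The next comparisons asked whether CA1 cells with a known target differ. Postsubiculum-projecting cells, which lie in dorsal CA1, held 19.4 ± 7.46 CPM of Slc6a2, the noradrenaline transporter gene, with no read in dorsal CA1 libraries, at least 163-fold higher (adjusted p = 0.000181). Dnah6 had no read there against 20.3 ± 3.34 CPM (adjusted p = 0.00017), and Gabrd, a GABA receptor subunit, and Tmem132a were 36.1-fold and 24.9-fold lower. The muscarinic receptor Chrm1 stood at 145 ± 6.29 against 390 ± 23.8 CPM (adjusted p = 3.86e-05). Lars2 was 17.1-fold lower, at 616 ± 30.5 against 10700 ± 956 CPM, and is uncertain because its annotated gene holds a stretch nearly identical to mitochondrial ribosomal RNA. Of 12663 genes 1370 were called, 663 higher in projecting and 707 in dorsal CA1 cells. The balance was 232 and 533 in the fit to all 48 libraries and 869 and 730 under voom. Reads outside annotated genes made up 43.0% in projecting and 29.4% in dorsal CA1 libraries. Without dorsal replicates 1, 2 and 3 the count was 589, 498 and 650. Fth-ps2, Slain1os, Cdc14b, Cfp and Slc7a5, the other ranked genes, lost their call in at least 1 omission of a library, and Dnah6 and Tmem132a lost theirs on FPKM.

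Of 79 oxidative phosphorylation genes 16 were lower in postsubiculum-projecting cells and 1 was higher, 21 adjusted over the list alone (camera adjusted p = 1.72e-05; adjusted p = 0.629 with an estimated correlation), with Atp5a1 at 200 ± 53.2 against 646 ± 45.7 CPM. Of 16 GABA receptor genes 5 were higher and 2 lower, 9 adjusted over the list alone (Fisher adjusted p = 0.00808), with Gabbr2 at 632 ± 12.7 against 344 ± 17.3 CPM. Of 8 neuropeptide genes 4 were lower and 1 higher, 5 adjusted over the list alone (Fisher adjusted p = 0.00808), with Chgb at 561 ± 70.9 against 1020 ± 106 CPM. Amygdala-projecting and accumbens-projecting cells of ventral CA1 differed in 3 of 12981 genes, all higher in accumbens-projecting cells: Dlk1 at 69.5 ± 96.9 against 0.0848 ± 0.0764 CPM, the metabotropic receptor Grm2 at 13.3 ± 7.99 against 0.0172 CPM, and the adhesion gene Alcam at 91.2 ± 59.2 against 7.84 ± 2.78 CPM (adjusted p = 0.0161 for each). No gene was higher in amygdala-projecting cells by edgeR in this fit, against 45 without a low-count filter and 152 with all 48 libraries in the fit. The number of genes at an unadjusted p under 0.05 was 1193, voom with quality weights called 0 genes and DESeq2 386. Each of the 3 genes lost its call without any one amygdala-projecting library. The count was 0 without amygdala-projecting replicate 2 or 3, 1 without accumbens-projecting replicate 1 and 11 without accumbens-projecting replicate 3. By correlation 1 of 3 amygdala-projecting and 0 of 3 accumbens-projecting libraries were most like their own group, and accumbens-projecting replicate 3 held interneuron genes, with Sst at 516 CPM. Subiculum markers had 0 of 4 called, 1 adjusted over the list alone (camera adjusted p = 0.356).

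The long axis was then compared in CA3 and DG. In CA3 the iodotyrosine deiodinase gene Iyd stood at 48.6 ± 7.85 CPM in dorsal and 0.526 CPM in ventral cells, 92.3-fold apart (adjusted p = 0.000189), and the synaptic vesicle gene Rph3a at 648 ± 110 and 14 ± 18.3 CPM (adjusted p = 0.00155). Ventral CA3 held 251 ± 179 CPM of Vgll3 against 0.0357 CPM, a ratio that counting error placed between 1930 and 57700, and 73.1 ± 35.9 CPM of Adcyap1, the gene for the neuropeptide PACAP, against 0.211 CPM (adjusted p = 3.65e-06). Cd38, Sema3c and Qpct were the other genes ranked highest in dorsal CA3, at 17.7, 21.7 and 11.4 CPM. Tmem132c and the potassium channel subunit Kcnmb2 had no read in dorsal CA3 and were at least 93.1-fold and 83.4-fold higher in ventral CA3. Of 15549 genes 773 were called, 388 higher in dorsal and 385 in ventral CA3. Of 7 CA1 markers 5 were higher in ventral and 1 in dorsal CA3, 6 adjusted over the list alone (camera adjusted p = 0.000212; adjusted p = 0.0131 with an estimated correlation), with Fibcd1 at 7.03 ± 3.49 against 0.425 ± 0.607 CPM. Of 8 long-axis ventral genes 3 were higher in ventral CA3 and 1, Htr2c, in dorsal, 5 adjusted over the list alone (camera adjusted p = 8.99e-06; adjusted p = 0.00614 with an estimated correlation). Of 6 long-axis dorsal genes 3, namely Ndst4, Lefty1 and Wfs1, were instead higher in ventral CA3, 3 adjusted over the list alone (camera adjusted p = 0.00416; adjusted p = 0.0425 with an estimated correlation). Of 7 CA3 markers 3 were higher in dorsal and 1, Coch, in ventral cells, 5 adjusted over the list alone (camera adjusted p = 0.00134; adjusted p = 0.018 with an estimated correlation). The dopamine receptor Drd2 lost its call without dorsal replicate 2 or 3 or ventral replicate 3, and the count was 454 and 436 without dorsal replicates 2 and 3 and 452 without ventral replicate 2.

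In DG genes of energy metabolism were higher in dorsal cells. Of 80 oxidative phosphorylation genes 45 were higher in dorsal and 1 in ventral granule cells, 54 adjusted over the list alone (camera adjusted p = 1.17e-18; adjusted p = 0.00315 with an estimated correlation), with Cox6a1 at 293 ± 84.1 against 69.3 ± 10.5 CPM and Atp5g1 at 282 ± 35.8 against 103 ± 9.4 CPM. Library measures differed as well. Mean depth was 7.17 ± 0.595 M reads in dorsal and 15.6 ± 0.855 M in ventral DG, ERCC shares were 2.68% to 4.06% and 0.969% to 1.33%, genes with at least 5 reads numbered 11714 to 12008 and 14389 to 15223, and replicates correlated at 0.844 to 0.852 and 0.956 to 0.959. All 8 long-axis ventral genes were higher in ventral DG, 8 adjusted over the list alone (camera adjusted p = 9.23e-06; adjusted p = 0.0187 with an estimated correlation), with Grp, gastrin-releasing peptide, at 1.2 ± 1.17 against 69.2 ± 16.6 CPM and Trhr, a thyrotropin-releasing hormone receptor, at 1.4 ± 2.43 against 186 ± 32.1 CPM. Immediate-early genes had 7 of 18 higher in dorsal DG and 0 in ventral, 7 adjusted over the list alone (camera adjusted p = 0.000146; adjusted p = 0.143 with an estimated correlation), with Egr1 at 462 ± 173 against 113 ± 32.1 CPM. Of 8 DG granule markers 2 were higher in dorsal DG, 2 adjusted over the list alone (camera adjusted p = 0.000733; adjusted p = 0.0581 with an estimated correlation), with Dsp, desmoplakin, at 366 ± 41.6 against 25.6 ± 6.36 CPM. Prox1 stood at 1200 ± 242 and 1390 ± 83.7 CPM and was not called. Of 68 cell adhesion genes 25 were higher in ventral and 6 in dorsal DG, 39 adjusted over the list alone (camera adjusted p = 0.0023; adjusted p = 0.11 with an estimated correlation), with Ntm at 0.621 ± 0.42 against 60.7 ± 13 CPM. The sodium channel Scn7a and the protease Adamts9 had no dorsal read and were at least 98.1-fold and 89.4-fold higher in ventral DG. Tnnt2 and Pla2g2f had no ventral read and stood at 38.6 ± 45.3 and 17.8 ± 8.89 CPM in dorsal DG. Xist, expressed from the inactive X chromosome, was higher in dorsal DG (2040 ± 1760 against 12.2 ± 0.891 CPM, adjusted p = 0.0341), 1 of 5 sex-linked genes called. This rested on dorsal replicates 2 and 3, at 3070 and 3040 CPM, while replicate 1 held 6.16 CPM. Every ventral library held more of the Y-linked gene Ddx3y than of Xist. Sex-linked expression thus ran partly with the DG long axis, and the part of sex was not tested. Of 15549 genes 3010 were called, 1355 higher in dorsal and 1655 in ventral DG, and 2002 were called without ventral replicate 3. The balance turned to 600 and 275 under voom and to 2533 and 1076 with the length trend removed.

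Interactions tested whether the long-axis difference in CA1 differs from that in another region. It differed from CA3 for 547 genes, 203 of them with a difference more toward dorsal in CA1 and 344 more toward ventral, and from DG for 1510 genes, 792 and 718. The latter balance turned to 253 and 439 under voom and to 515 and 1388 with the length trend removed. Lct was higher in dorsal cells in all 3 regions, at 29.4 against 3.38 CPM in CA3 and 172 against 6.47 CPM in DG. Scn4b was higher in dorsal CA1 and in dorsal CA3, where it stood at 16.6 against 3.76 CPM. Robo3 was higher in dorsal CA1 and in dorsal DG (78 against 0.613 CPM). Npy went the opposite way in DG, with 2.88 CPM in dorsal and no read in ventral cells. The oxidative phosphorylation list differed between CA1 and DG, with 24 of 80 genes less dorsal in CA1 and 0 the other way, 41 adjusted over the list alone (camera adjusted p = 3.15e-14; adjusted p = 0.0121 with an estimated correlation). Of 6 long-axis dorsal genes 4 were more dorsal in CA1 than in CA3, 4 adjusted over the list alone (camera adjusted p = 9.97e-09; adjusted p = 0.00135 with an estimated correlation). The list, partly chosen from this study, is not independent evidence.

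Regions were compared by averaging their dorsal and ventral cells, with 6 libraries each. Against CA3, CA1 held more Mpped1 (189 ± 58.1 against 1.01 ± 0.943 CPM, adjusted p = 3.79e-14) and more Calb1 (121 ± 59.9 against 2.04 ± 2.1 CPM, adjusted p = 7.11e-07). CA3 held more of the protein kinase Prkcd, 64.5 ± 71.2 against 0.0494 CPM, and more Shisa2, 19.2 ± 12.4 against 0.109 CPM. Of 7 CA1 markers 6 were higher in CA1, 6 adjusted over the list alone (camera adjusted p = 1.64e-36; adjusted p = 3.86e-07 with an estimated correlation), and 6 of 7 CA3 markers were higher in CA3, 6 adjusted over the list alone (camera adjusted p = 1.62e-18; adjusted p = 9.31e-06 with an estimated correlation). CA2 markers went both ways, 2 higher in CA1 and 3 in CA3 of 7, 6 adjusted over the list alone (camera adjusted p = 0.16). Of 8 oligodendrocyte markers 5 were higher in CA3, 7 adjusted over the list alone (camera adjusted p = 0.0959), with Mobp at 7.47 ± 6.17 against 0.0399 CPM, while microglia markers had 0 of 3 called by edgeR, 0 adjusted over the list alone (camera adjusted p = 0.752). In all 2098 of 15549 genes were called, 830 higher in CA1 and 1268 in CA3.

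Against DG, CA1 held 17.9 ± 12.2 CPM of Lefty1 with no DG read, at least 62.2-fold higher (adjusted p = 4.48e-08), and 19 ± 2.95 CPM of the ephrin receptor Ephb3 against 0.0877 CPM (adjusted p = 6.74e-10). DG held 1300 ± 194 CPM of Prox1, a transcription factor of granule cells, against 1.43 ± 1.62 CPM in CA1 (adjusted p = 1.43e-05), and the neurotrophin Ntf3 at 20 ± 8.68 CPM with no CA1 read. All 7 CA1 markers were higher in CA1, 7 adjusted over the list alone (camera adjusted p = 3.78e-32; adjusted p = 1.35e-05 with an estimated correlation), and all 8 DG markers in DG, 8 adjusted over the list alone (camera adjusted p = 1.28e-16; adjusted p = 0.000372 with an estimated correlation). Of 5 GABAergic markers 3 were higher in DG than in CA1, 3 adjusted over the list alone (camera adjusted p = 0.00817; adjusted p = 0.0501 with an estimated correlation), with Gad1 at 61.6 ± 14.4 against 1.42 ± 1.62 CPM. The kainate receptor Grik3 stood at 8.23 ± 9.75 in CA1 and 90.3 ± 51.3 CPM in DG, and the semaphorin Sema5a at 5 ± 4.72 and 1050 ± 302 CPM. In all 5152 genes were called, 2713 higher in CA1 and 2439 in DG, a balance that turned to 2429 and 2720 with DESeq2's size factors and to 2746 and 3210 with its Wald test. Between CA3 and DG 5673 genes were called, 3044 higher in CA3 and 2629 in DG, which likewise turned to 2817 and 2874 and to 3078 and 3364. The opioid peptide gene Pdyn was 737-fold higher in DG (adjusted p = 1.46e-08) and Calb1 188-fold (adjusted p = 3.69e-08), while Mndal and Cd109 were 670-fold and 618-fold higher in CA3. Of 18 immediate-early genes 10 were higher in DG and 3 in CA3, 13 adjusted over the list alone (camera adjusted p = 0.00231; adjusted p = 0.319 with an estimated correlation), with Jun at 34 ± 18.2 against 236 ± 29.1 CPM.

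PV and SST interneurons were compared as a reference for the difference between classes of interneuron. PV cells held 65.3 ± 38.6 CPM of Pthlh, the parathyroid hormone-like hormone, against 0.0164 CPM (adjusted p = 0.0002), 528 ± 62.8 CPM of the synaptotagmin Syt2 against 1.33 ± 0.555 CPM (adjusted p = 5.61e-06) and 89.7 ± 28.1 CPM of the potassium channel subunit Kcng4 against 0.0492 CPM (adjusted p = 8.18e-05). SST cells held 26.2 ± 26.1 CPM of the somatostatin receptor Sstr1 and 20.2 ± 19.9 CPM of the nicotinic receptor Chrna2, each against 0.0123 CPM. Of 6 PV markers 5 were higher in PV cells, 6 adjusted over the list alone (camera adjusted p = 1.7e-26; adjusted p = 0.0244 with an estimated correlation), and 5 of 7 SST markers were higher in SST cells, 6 adjusted over the list alone (camera adjusted p = 3.1e-17; adjusted p = 0.0244 with an estimated correlation). Pvalb itself stood at 329 ± 34.3 against 25 ± 27 CPM (adjusted p = 0.0439) and lost its call without any PV library or SST replicate 1, and Sst at 652 ± 362 against 4650 ± 1760 CPM (adjusted p = 0.00657) lost it without SST replicate 3. Potassium channel genes were called often, 11 of 67 higher in PV and 6 in SST cells, 34 adjusted over the list alone (Fisher adjusted p = 2.3e-09). Of 6 microglia markers 2 were called, both higher in SST libraries, and 5 adjusted over the list alone (camera adjusted p = 6.41e-05; adjusted p = 0.312 with an estimated correlation), with C1qc at 16.8 ± 15.1 against 0.0645 CPM. Of 13633 genes 478 were called, 221 higher in PV and 257 in SST cells. The count was 230, 289 and 230 without PV replicates 1, 2 and 3.

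Genes called with at least a 3-fold difference were counted in pairs of populations with 3 libraries each. Dorsal and ventral CA1 differed in 704 genes, dorsal and ventral CA3 in 530 and dorsal and ventral DG in 429. Dorsal CA1 differed from dorsal CA3 in 1180 genes, from dorsal DG in 1366, from PV cells in 2833 and from SST cells in 2486. Called at any fold, CA3 gave 1540 and DG 775 genes in these fits of 6 libraries, against 773 and 3010 in the fit of 18. At 3-fold the fit of 18 gave 387 for CA3 and 1530 for DG, so the order of the long axes depends on the fit. PV and SST cells differed in 360 genes at 3-fold, superficial and deep CA1 in 146 and proximal and distal CA1 in 34. The dorsal-ventral difference in CA1 ranked 6 of 14 pairs by this count, by all called genes, at 2-fold, and at 3-fold with at least 5 CPM. Amygdala-projecting and accumbens-projecting cells gave 0 genes by edgeR when fitted without other groups, with 600 at an unadjusted p under 0.05.

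**Figure D3:**
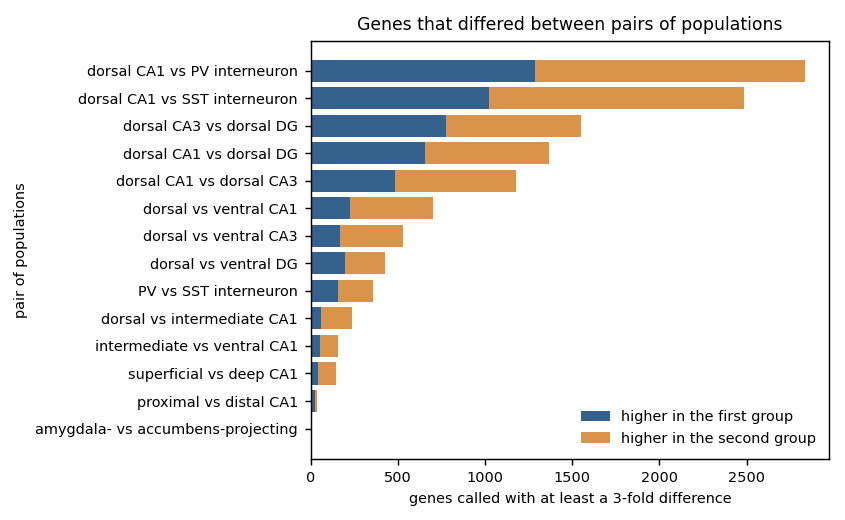
Number of genes called with at least a 3-fold difference (horizontal axis, from 0) in 14 pairs of populations (vertical axis) with 3 libraries each, split into genes higher in the first and in the second population. The pair of dorsal and ventral CA1, at 704 genes, stands between the pairs of different regions and the pairs within CA1.

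A long-axis score, defined above, set the other populations against the CA1 poles. Dorsal CA1 stood at 5.25, ventral CA1 at 0 and intermediate CA1 at 2.52, 48.1% of the way from ventral to dorsal. Distal CA1 stood at 5.76, postsubiculum-projecting CA1 at 5.22, proximal CA1 at 4.77, superficial CA1 at 4.18 and deep CA1 at 3.95. Amygdala-projecting and accumbens-projecting cells stood at 0.05 and -0.10, beside the ventral pole. Dorsal CA3 stood at 2.90 and ventral CA3 at 1.05, dorsal DG at 2.58 and ventral DG at 1.07. PV cells stood at 1.97 and SST cells at 1.57. A cell that reads few genes of either set scores near 0 whatever its kind, as ventral CA1 does, so values outside CA1 are no measure of ventral identity. Of the 13 other populations 7 had a score nearer that of ventral CA1, and 6 to 8 with 50 or 200 genes or another offset.

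**Figure D4:**
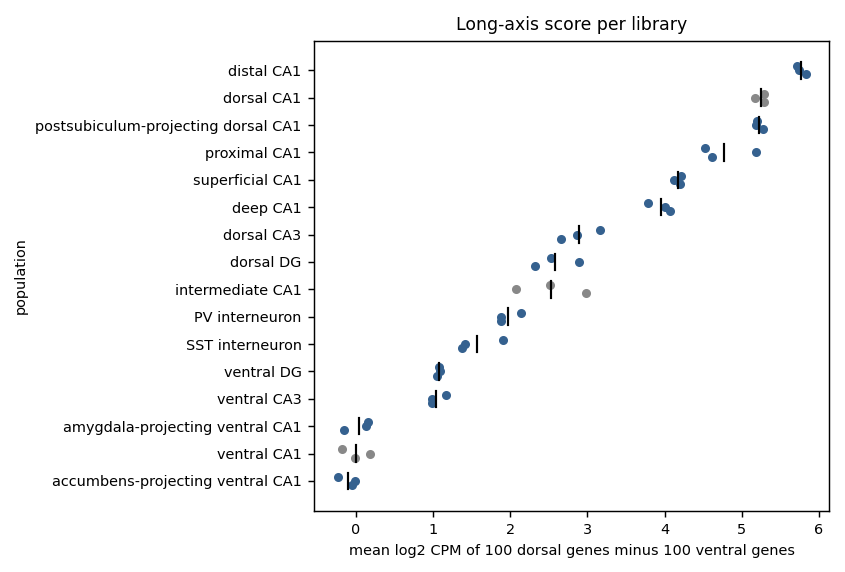
Long-axis score of each library (horizontal axis, difference of mean log2 CPM between 100 dorsal and 100 ventral genes) in the 16 populations (vertical axis); points are libraries, lines are means of 3, and grey points are the long-axis CA1 groups, of which dorsal and ventral defined the genes. The projection-defined ventral cells sit beside ventral CA1, and postsubiculum-projecting cells beside dorsal CA1.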

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

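The interactions were planned, and the tests of Npy against interneuron RNA were chosen after the result was seen. The interactions met the rule for a closer look since they test the difference between regions itself, and called 547 genes against CA3 and 1510 against DG. In 100 drawn splits that regrouped libraries within each region, 2 called as many genes in each case, the real one included. Most such splits mix dorsal and ventral libraries and so break up the long-axis difference of each region as well. They ask whether there is any long-axis difference, so they cannot exclude chance for the interaction. The highest other split called 1419 genes against CA3 and 2649 against DG, more than the real ones. In that split the dorsal and ventral libraries of one region were exchanged as whole groups, which makes the interaction the sum of both long-axis differences. It points to the structure of the samples, and the highest split without such an exchange called 360 and 910 genes.

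Values below are the log2 long-axis difference in CA1 minus that in the other region, positive for a difference more toward dorsal in CA1. The genes were the 20 ranked by their difference between dorsal and ventral CA1, a choice that favours interactions, and only the 11 of 20 that differed from CA3 and the 12 of 20 that differed from DG are given. Against CA3 they were 10.53 for Scn4b, 10.32 for Dnah6, 9.46 for Egfl6, 6.86 for Robo3 and 5.64 for Lct. On the ventral side they were -13.98 for Npy, -9.39 for Dcn, -8.36 for Kitl, -8.17 for Igfbp5, -7.76 for Kctd12b and -7.74 for Ndrg1. Against DG they were 13.01 for Egfl6, 11.92 for Scn4b, 11.30 for Plekhg1, 6.06 for Dnah6, 4.05 for Olfm3 and 4.02 for Lct, and on the ventral side -20.10 for Npy, -13.77 for Irs4, -12.16 for Kctd12b, -9.06 for Igfbp5, -8.55 for Col6a1 and -5.75 for Ndrg1. Several rest on groups without a read, among them Npy, Irs4, Scn4b, Dnah6, Egfl6 and Plekhg1, so their size depends on the fit and is no bound. Npy against CA3 lost its call without dorsal CA3 replicate 1 (-11.45), after thinning (-9.73) and in the fit to all 48 libraries (-14.09), and Irs4 against DG without dorsal DG replicate 3 (-10.97) and with DESeq2 (-13.14). Robo3 against CA3 and Lct against DG lost theirs on FPKM, at 1.34 and 0.54, and Lct also in the fit to all 48 libraries (4.07).

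Npy was read in every intermediate and ventral CA1 library and in none of dorsal CA1. If it came with RNA of SST interneurons, the ratio of Sst to Npy would be at or above 1.55, the lowest among SST interneuron libraries, but it lay between 0.031 and 0.327 in the 6 CA1 libraries, so 0 of 6 reached it. For PV interneurons the ratio of 4 summed GABAergic genes to Npy would be at or above 6.21, but it lay between 0.844 and 1.77, so again 0 of 6 reached it. Other interneurons rich in Npy, a difference between batches and a difference between CA1 cells stay open, all untested. Npy did not follow the long axis in superficial, deep, amygdala-projecting and accumbens-projecting cells (17.8, 9.55, 1.17 and 4.32 CPM). Nor did Irs4, with 13.2 CPM in superficial cells and no read in either projecting group. Both followed it in proximal, distal and postsubiculum-projecting cells, with Irs4 up to 0.0447 CPM per library.

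ERCC spike-ins lay outside every comparison, with the highest share at 8.29% of reads in ventral CA1 replicate 1.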

How the results depend on the processing

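Thinning, the length trend's removal, and omissions of libraries for the position and peaks of intermediate CA1 were chosen after seeing the data. Counts within 1.5 times of the reported one are not repeated, and the cause of the differences below was not tested. With all 48 libraries in 1 fit, 665 genes were called between dorsal and ventral CA1, 101 between dorsal and intermediate, 80 between intermediate and ventral, 65 between superficial and deep, 354 between amygdala-projecting and accumbens-projecting, 765 for postsubiculum-projecting cells, 438 for CA3, 1883 for DG, 1120 for PV against SST cells, 296 and 792 for the interactions with CA3 and DG, and 2 peaking in intermediate cells. The DESeq2 Wald test called 979 between dorsal and intermediate, 1028 between intermediate and ventral, 778 between proximal and distal, 915 between superficial and deep, 386 between amygdala-projecting and accumbens-projecting, 2780 for postsubiculum-projecting cells, 1186 for CA3, 1487 for PV against SST, and 891 and 2543 for the interactions. Voom with quality weights called 237 between proximal and distal, 0 between amygdala-projecting and accumbens-projecting, 2463 for CA3, 875 for DG, 3685 between CA1 and CA3, 1183 for PV against SST, and 1394 and 692 for the interactions. Without a low-count filter the counts were 301 for proximal against distal, 511 for superficial against deep, 180 for amygdala against accumbens and 864 for PV against SST. On FPKM, for which fewer genes were tested, they were 223 for dorsal against intermediate, 353 for intermediate against ventral, 53 for proximal against distal, 89 for superficial against deep and 0 for amygdala against accumbens. For amygdala against accumbens thinning and the replicate block each called 1. The replicate numbers did not pair the samples, since no pair of groups had correlations above 0.1 for all 3 numbers, and the block moved no other count by over 1.5 times. Between superficial and deep cells each library correlated best with that of its own number, at 0.017 to 0.053, a hint from the data alone. Dcn between dorsal and ventral CA1 was not called under the block. Fits of only the 2 groups, 6 libraries, called 1540 genes for CA3 and 775 for DG. DESeq2's size factors in edgeR moved no count by over 1.5 times. Camera calls fell from 98 to 29 with an estimated correlation.

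Leaving out 1 library gave 1361 to 1670 genes for dorsal against ventral CA1, 315 to 627 for dorsal against intermediate, 399 to 539 for intermediate against ventral, 16 to 94 for proximal against distal, 85 to 280 for superficial against deep, 0 to 11 for amygdala against accumbens, 498 to 1329 for postsubiculum-projecting cells, 436 to 659 for CA3, 2002 to 3419 for DG, 1719 to 1903 for CA1 against CA3, 4418 to 5695 for CA1 against DG, 4953 to 6256 for CA3 against DG, 230 to 683 for PV against SST, 385 to 567 and 1035 to 2161 for the interactions, and 8 to 22 peaking genes. The position of intermediate CA1 ranged from 0.475 to 0.576. Of the 20 genes ranked between dorsal and ventral CA1, 17 were called in every setting, against 5 of 10 for dorsal against intermediate, 2 of 10 for intermediate against ventral, 3 of 16 on the transverse and 3 of 16 on the radial axis, 3 of 10 for postsubiculum-projecting cells and 0 of 3 for amygdala against accumbens. Some directions reversed: Pvalb between proximal and distal at -6.42 without proximal CA1 replicate 1 (up to 1.71 without proximal CA1 replicate 3), Calb2 between CA1 and CA3 at 0.034 without dorsal CA3 replicate 1 (down to -4.07 without dorsal CA1 replicate 3), and on FPKM Mpped1 at -0.18 in the interaction with CA3 and Zbtb20 at -0.40 in that with DG. The share of called genes higher in dorsal DG moved from 45% to 68.6% under voom and to 70.2% without the length trend, and that of genes higher in proximal cells from 77% to 64.8% with DESeq2 and to 88.4% in the fit to all libraries. That of genes more toward dorsal in CA1 than in DG moved from 52.5% to 36.6% under voom and 27.1% without the length trend, and that of genes higher in postsubiculum-projecting cells from 48.4% to 30.3% in the fit to all libraries. At these depths the simulated recovery of 2-fold changes was 3 to 43 of 100 per comparison, so most changes of that size would go uncalled.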

Other observations

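Thinning and the length trend's removal were chosen after the data were seen, their tests were written before their results, and the other splits were planned. Dorsal CA1 had more reads than ventral CA1, so depth was weighed for the 1837 genes called between the poles. ERCC shares also differed, 0.511% to 1.01% in dorsal and 2.72% to 8.29% in ventral CA1, untested as a cause. With libraries thinned to the shallowest, 1750 genes were called, 1649 of them among the 1837. With the trend on exon length removed, 1849 were called, 1797 of them shared. Depth or length as the main cause needed a fall by over 1.5 times, which neither gave. Read number alone thus did not make the calls. Thinning keeps expected ratios, so other differences that go with depth stay open, as do batch and biological ones.

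Oxidative phosphorylation genes stood higher in dorsal than in ventral DG, at a median log2 difference of 0.90 over 80 genes, while dorsal DG had fewer reads. The median was 0.925 after thinning and 1.255 after removal of the length trend, which moved the median of all genes to 0.27. Voom with quality weights gave 0.85 with a median of all genes of -0.26, and every setting kept a median above 0, between 0.777 and 1.255. Gene length as the whole cause needed a median under 0.5 times 0.902, which removal of the length trend did not give. The same bound for depth was not reached, but thinning keeps expected ratios, so its median decides nothing about depth. RNA quality, batch and a difference between the cells may each account for it, and none was tested.

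Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called the most genes in each, 1 of 10, and the real count and the highest other were 1837 and 0 for dorsal against ventral CA1, 599 and 0 for dorsal against intermediate, 611 and 0 for intermediate against ventral, 135 and 0 for proximal against distal, and 311 and 0 for superficial against deep. They were 3 and 2 for amygdala-projecting against accumbens-projecting cells, 1370 and 0 for postsubiculum-projecting cells, 773 and 2 for CA3, 3010 and 5 for DG, and 478 and 0 for PV against SST cells. With 6 libraries against 6, 100 drawn splits excluded chance, since 1 of 100, the real one, called as many as 2098 genes for CA1 against CA3 (highest other 871), 5152 for CA1 against DG (2214) and 5673 for CA3 against DG (2394).

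Xist and the Y-linked gene Ddx3y parted the libraries, with Xist higher in 11, Ddx3y higher in 37, and both kinds in 6 of the 16 populations. Xist stood at 909 and 1251 CPM without TMM scaling in 2 of the 3 intermediate CA1 libraries and at 3.01 CPM in the third, and ventral and dorsal CA1 held the Ddx3y kind alone. Kl, a gene on the choroid plexus list, was read in CA1 cells themselves, at 55.2 ± 18.9 CPM in dorsal, 36.1 ± 5.29 in intermediate, 4.07 ± 1.05 in ventral and 77.1 ± 4.62 in postsubiculum-projecting cells. The vesicular glutamate transporter gene Slc17a6 stood at 20.6 ± 12.1 CPM in deep CA1 and at 13.5 ± 0.777 CPM in ventral against 0.304 CPM in dorsal DG.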
